A study of Mus musculus with 3 samples.

How the data were processed

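The series compared mouse cells labelled as embryonic stem cells in 3 groups, wildtype, LIFR knockout and gp130 knockout, with 1 array in each, and the group of each array was taken from its label. Per the labels, total RNA was extracted with Trizol and Cy3-labelled cRNA was hybridised to single-colour Agilent arrays. Per the file headers, the arrays were of design 026655, built on mm9, and were extracted with Feature Extraction 11.0.1.1 and the protocol GE1_1100_Jul11, while the submitters' processing notes name Feature Extraction 9.1. All 3 arrays gave 1 distinct scan in the headers, so no batch could be set against genotype. No array coordinates are given, since the gene table used for names is of assembly GRCm38.p6.

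The deposited intensity of each spot is the scanner software's processed signal, per the file headers a background-subtracted and detrended brightness that is not normalised between arrays. The deposited median intensity of the spot and of its local background was used for the alternative background correction. The deposited flags of the software, per the file headers, are another kind of value of 0 or 1 and mark spots well above background, saturated spots and outliers. The log2 values of the authors' series matrix had a median of 5.38 in each of the 3 columns and correlated across probes with the log2 processed signal at r = 0.996, 0.999 and 0.995 on the wildtype, LIFR knockout and gp130 knockout arrays. Their log2 scale was found by this comparison, the equal column medians are those of a between-array normalisation, and what method the authors used and how they set the floor are not given in the sources used here.

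Each array held 44397 spots, 43020 of them for 39429 non-control probes, of which 399 had several spots. Outlier spots, 97 on the wildtype, 222 on the LIFR knockout and 138 on the gp130 knockout array, were left out, no spot was saturated, and spots of a probe were averaged. The log2 processed signal minus the array's 75th percentile was the main value, with percentiles at signals of 664, 750 and 652. Accessions in the files were matched without versions to the gene table, which named 27234 of 39429 probes (69.1%) and 20659 genes, and 12195 probes stayed unnamed. Each gene was read from the probe with the highest mean over the 3 arrays, and other probes are quoted where they differ.

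A gene entered a comparison when its probe was well above background on at least 1 of its 2 arrays. Where the other array was not, the ratio is a lower bound, the bright value against the higher of the dim probe's own value and the lowest signal well above background on that array, among probe means, which was 6.94, 16.7 and 9.66 on the wildtype, LIFR knockout and gp130 knockout arrays. The wildtype value is that of a probe with 10 spots, 5 of them well above background, and lies under the lowest such spot, 10.5, so that bounds over a dim wildtype value are up to 1.51-fold larger than with that spot as the floor. Where the bright value did not exceed this floor, the ratio was set to 0. Bounds, with these values of 0, entered the list medians. Genes with a ratio of at least 2-fold were counted. From the scatter of repeated spots, a ratio of 2 spots has a 95% half-width of 0.147 on the log2 scale, or 1.11-fold, which leaves out the scatter between cultures. It holds for the median probe, and the 90th percentile of the SD, 0.167, 0.130 and 0.178 on the 3 arrays, gives many probes a wider one. Since there were no replicates, no test was run.

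There were 28 gene lists, fixed before the data were examined, with 682 of 695 entries on the array. The lists covered LIF-STAT3 targets, gp130 family genes, JAK-STAT components, pluripotency states, germ layers and other cell types, signalling targets, stress, metabolism, imprinting, cell cycle, ribosomal proteins, DNA methylation and sex-linked genes. The median ratio of each list's measured members was given as a percentile among 10000 random lists of the same size matched on mean signal in 20 bins, as a description of these arrays. Lists with fewer than 3 measured members got no median. Of 81 medians, 25 lay outside the central 95% of random lists, where lists of genes drawn at random would give 4.05. The genes of a real list may move together, and some genes are in several lists. The comparisons also share the same arrays, so 4.05 is no measure of chance for these lists.

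The genes named in the text were chosen by a rule fixed before the data were examined. It takes Lifr and Il6st, the 8 genes with the largest ratio each way per comparison among genes well above background on both arrays and at least 2-fold the same way under normexp, and the 3 largest bounds each way per knockout. It also takes up to 4 members per list past 2-fold in either knockout, the 2 brightest members of the LIF-STAT3 and pluripotency lists, the 6 genes each way with the largest smaller ratio in both knockouts, and the genes that went opposite ways. Clone and predicted-gene names were passed over. The normexp condition used the fit that includes the stray signal, as fixed, and left 7 higher genes for the gp130 knockout. The rule was run again without the spots in stray signal, after seeing the data. Further genes were chosen after their values were seen, namely undetected pluripotency genes, Nanog, Pou5f1, Gata6, Apoe, the histone genes as a group and members that differed between the knockouts.

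Regions of stray signal were marked after seeing the data. A spot was marked where at least 40% of at least 5 neighbouring probes within 4 spots on each side that were dim on the other arrays were well above background on this one, or where its local background was over 2 times the array's median. This marked 15, 578 and 436 spots on the wildtype, LIFR knockout and gp130 knockout arrays. Later marker lists were written for embryonic stem cells, epithelium, stratified epithelium, fibroblasts, blood, endothelium, neurons, hepatocytes, muscle, and NF-kB and inflammatory cytokine genes.

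Alternatives fixed beforehand were normexp with an offset of 50, median scaling, quantile and cyclic loess normalisation, the series matrix values, other filters on dim probes, the mean of a gene's probes, outlier spots kept, a 4-fold threshold and random lists not matched on signal. The files hold no mean signal, so normexp was run on the median signal. The choice of leaving out stray signal, of fitting normexp without it and of a floor from single spots came after the data were seen. Unchanged arrays sharing 1 wildtype array were simulated 100 times, drawing each array's scatter from the ratios between the knockout arrays within bins of mean signal. For the scatter of single spots, bright repeated spots of probes with at least 5 spots were set against the median of the other spots of their probe, with population outliers kept because that flag needs repeated spots.

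The single values of some members of the gene lists are not reported here, though the lists' medians include them. The steps were tested on simulated data, with scatter drawn from a normal distribution. The changed genes were drawn only from those more than 2-fold above the highest floor of the 3 arrays. The shares of changed genes called therefore do not speak for dimmer genes, such as many of those read as bounds. For the LIFR knockout against wildtype, with 15367 genes, 98.5% of genes changed 3-fold, 100% of those changed 6-fold and 7.04% of those changed 1.5-fold were called, with 0.804% of unchanged genes. For the gp130 knockout against wildtype, with 16109 genes, the shares were 100%, 100%, 0% and 0.955%, and between the knockouts, with 14767 genes, 100%, 100%, 5.56% and 0.494%. Of 200 unshifted lists of genes drawn at random, 94.5%, 95.5% and 93.5% fell inside the central 95% in these comparisons, and a shifted list lay at percentile 100 in each. The stray signal rule found 97.2% of 424 spots lit on the wildtype array and marked 0.176% of spots outside, against 0.0352% on the real array. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 were used.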

Results

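Gene expression was measured in mouse cells that the labels describe as embryonic stem cells of 3 genotypes, wildtype, LIFR knockout and gp130 knockout. LIFR is the receptor of the cytokine LIF, which is used to keep mouse embryonic stem cells in the pluripotent state, and gp130, encoded by Il6st, is the signalling partner that LIFR shares with the receptors of the IL-6 family. Single-colour Agilent arrays were used, with 1 array per genotype. There were no replicates, so no test, p-value or error between cultures was possible, and every difference is a difference between 2 arrays. Each array held 39429 probes, of which 25373 (64.4%) were well above background on the wildtype array, 22974 (58.3%) on the LIFR knockout array and 25817 (65.5%) on the gp130 knockout array. Spots of the same probe within an array differed little, with a median SD of 0.053, 0.048 and 0.052 on the log2 scale, which covers the scatter of spots and not that of cultures. The number of arrays limits the precision of every value.

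The probes of the targeted genes did not separate the genotypes. The Lifr probe that was well above background had a signal of 34.9 on the wildtype, 29.97 on the LIFR knockout and 34.7 on the gp130 knockout array, a log2 ratio of -0.39 for the LIFR knockout over wildtype with a scanner error of 0.28. The other Lifr probes were not well above background on any array. The Il6st probe gave 329, 369 and 299, a log2 ratio of -0.11 for the gp130 knockout over wildtype with a scanner error of 0.20. Where these probes lie relative to the deleted parts was not given in the sources used here, and a probe outside the deleted part checks nothing. The genotypes are therefore those of the labels, and each array is called by its label.

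Several known pluripotency genes were not detected on any array, the wildtype array included, though as wholes the pluripotency lists were detected about as often as all genes or more often. Of the 27 genes of the naive pluripotency list on the array, 16 (59.3%) were well above background on all 3 arrays and 10 on none. Of the 21 genes of the general pluripotency list, 16 (76.2%) were so on all 3 arrays and 4 on none, against 63.6% of all named genes on all 3. Sox2, Zfp42, Dppa3, Fgf4 and Nr0b1, all known as genes of mouse embryonic stem cells, were not well above background on any array. Pou5f1, the gene of the pluripotency factor Oct4, had a signal of 31.2, 22.7 and 20.3 on the wildtype, LIFR knockout and gp130 knockout arrays, and Nanog had 316, 217 and 329. Lin28a, at 727, 536 and 821, was clearly detected. So was 1 Tdgf1 probe, at 508, 632 and 477, while the others of its 3 probes were not well above background on any array. All 24 genes of a list of epithelial markers, written after these pluripotency values had been seen, were well above background on all 3 arrays, among them the keratin gene Krt18 at 39533, 50636 and 41452 and the E-cadherin gene Cdh1 at 9179, 11916 and 9836.

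**Figure D1:**
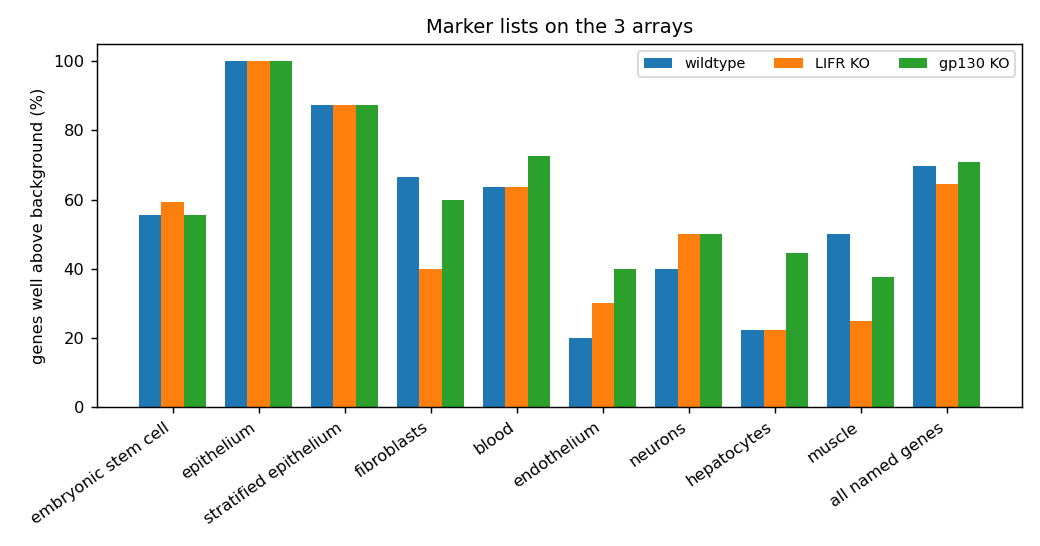
Percentage of the genes of each marker list that were well above background on each of the 3 arrays, with 1 bar per array and list, drawn from 0. Of the embryonic stem cell list, 55.6% were well above background on the wildtype array and 59.3% on the LIFR knockout array, against 100% of the epithelium list on every array.

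The first comparison asks which genes differed between the LIFR knockout and the wildtype array. Several genes of secreted inflammatory signals were far lower on the LIFR knockout array. Cxcl1, Cxcl5 and Cxcl3, genes of chemokines that attract neutrophils, were 14.6-fold, 7.31-fold and 4.12-fold lower, Csf3, the gene of the granulocyte growth factor G-CSF, 9.62-fold lower, and the monocyte chemokine gene Ccl2 5.997-fold lower. Lif, the gene of the ligand of the receptor itself, was 6.70-fold lower. On the higher side stood Bmf, a gene of a pro-apoptotic BCL2 family protein, at 11.7-fold, Frat1, whose product binds the kinase GSK3, at 10.4-fold, and the circadian clock gene Per1 at 6.77-fold. Foxj1, a regulator of motile cilia, was 5.54-fold higher and the hyaluronidase gene Hyal1 5.68-fold higher.

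Of 14554 genes compared, 417 were at least 2-fold higher and 236 at least 2-fold lower on the LIFR knockout array, of which 164 and 59 rested on a bound because 1 array was not well above background. The bounds over a dim wildtype value rest on a floor of 6.94 on that array, and with a floor of 10.5, an alternative chosen after seeing the data, 381 genes were higher. The transcription factor gene Cebpd was 4.03-fold lower and Adamts1, a gene of a secreted protease, 3.92-fold lower. Ypel2 was 5.48-fold higher and Zkscan14 5.80-fold higher. Among genes known only by a bound, Olfr1487, Rinl and Akna were at least 6.61-fold, 4.37-fold and 4.30-fold lower, and Hhla1, Peg12 and Acta1 were at least 8.68-fold, 7.86-fold and 7.32-fold higher, or 6.77-fold, 5.198-fold and 4.84-fold with the floor of 10.5.

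A stray signal lay over part of the LIFR knockout array and moved with its higher genes. Local background there reached 25884, against a median of 23.5 on that array and a highest value of 57 on the wildtype array. Of the 417 higher genes, 91 (21.8%) had their spot in such a region, against 1.97% of all genes compared and 2 of the 236 lower genes. They included Npc1l1, Ubxn7, Sord, Sap30bp and Rnft1, which ranked among the 8 highest with log2 ratios of 9.63, 7.21, 6.86, 5.31 and 3.21, and Zbtb46, Prrg3 and Mlc1, which had the 3 highest bounds. Other probes of Ubxn7, Sap30bp and Rnft1 outside the region gave log2 ratios of -0.01, 0.22 and -0.00394. With the spots in stray signal left out, an alternative chosen after seeing the data, 327 genes were higher and 233 lower. Zkscan14, Hyal1, Ypel2, Hhla1, Peg12 and Acta1 were named from this repeat.

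**Figure D2:**
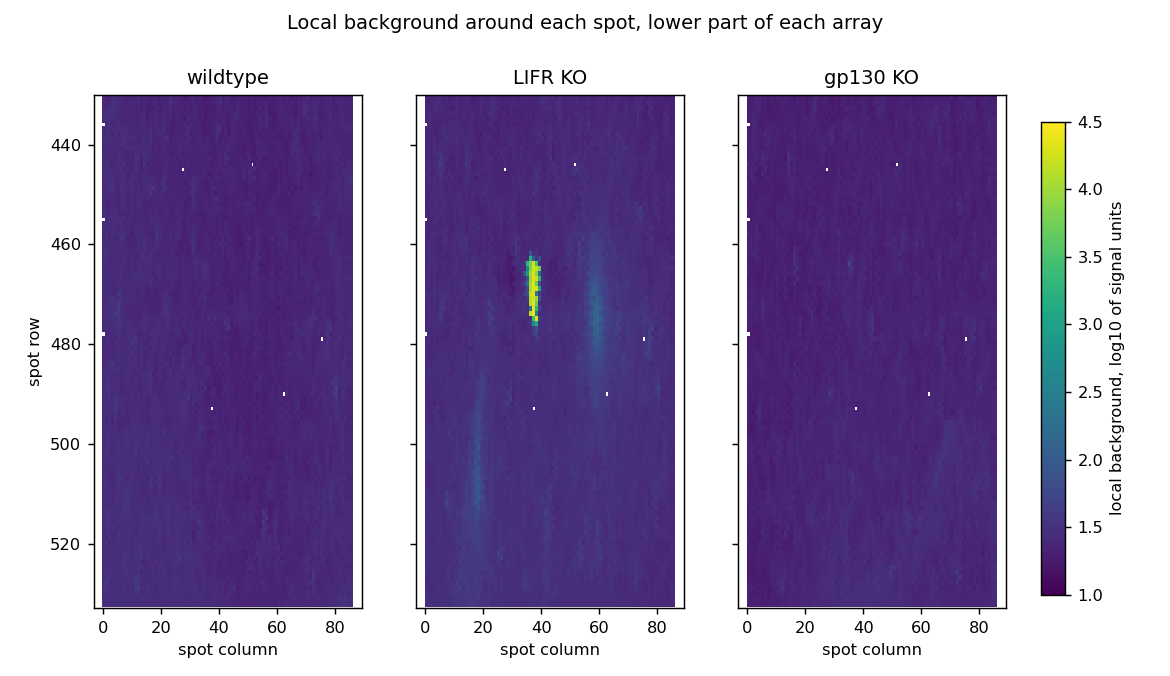
Local background around each spot in the lower part of each array, as log10 of the signal units, with spot columns and rows as axes. The LIFR knockout array reached 25884 in a narrow streak, while the wildtype and gp130 knockout arrays stayed at or below 57 and 51.

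Genes downstream of LIF and STAT3 went both ways on the LIFR knockout array. Of 20 measured members, 4 were at least 2-fold higher, Fos at 4.27-fold, the kinase gene Pim1 at 3.33-fold, the feedback inhibitor gene Socs3 at 2.58-fold and Junb at 2.44-fold. Myc was 3.54-fold lower and Ier3 2.76-fold lower, while Cebpb had a log2 ratio of 0.30. The median log2 ratio of 0.07 lay at percentile 88.3 of 10000 random lists matched on mean signal, and at 99.6 with a median of 0.19 without the stray signal. Among the receptors and ligands of the gp130 family, none of 11 measured members was 2-fold higher and 3 were lower, namely Lif, the ligand gene Clcf1 at 2.98-fold and Il6 at a bound of 2.46-fold, with a median of -0.17 at percentile 21.2. JAK-STAT components and negative regulators had no member past 2-fold among 20 and a median of -0.02 at percentile 49.6.

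No measured pluripotency gene passed 2-fold on the LIFR knockout array. The 17 naive genes had a median of -0.33 at percentile 0.62, with Nanog at -0.72, Klf5 at -0.68 and Zfp296 at -0.13, and the median was 0.05 at percentile 45.8 with no filter on dim probes. With the normexp background correction it was 0.34, still low among random lists at percentile 8.02, and -0.21 at percentile 1.98 when fitted without the stray signal. It lay outside the central 95% of random lists in 6 of 13 alternative settings. The 16 general pluripotency genes had a median of -0.22 at percentile 3.75, with Pou5f1 at -0.63, Cdh1 at 0.20 and Mybl2 at -0.10. These lists were only partly above background on every array, as given above. The formative and primed epiblast genes had a median of 0.01 at percentile 85.1, and the 5 measured genes of the 2-cell-like state -0.38 at percentile 0.92, both with no member past 2-fold. The 2-cell-like median ranged from -0.69 to -0.14 over 13 alternative settings. It lay outside the central 95% in 12, with a highest percentile of 4.57.

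Growth factor response genes were lower, and BMP target genes higher, on the LIFR knockout array. Of 21 measured MEK-ERK response genes 5 were lower, with Egr1 at 4.496-fold, Fosl1 at 2.98-fold and Phlda1 at 2.25-fold beside Myc and Ier3, and Fos alone was higher, with a median of -0.29 at percentile 0.1, or -0.12 at percentile 8.36 with normexp. Of 13 measured BMP target genes 4 were higher and none lower, with Hey1 at 3.52-fold, Id2 at 3.18-fold, Smad6 at 2.43-fold and Id1 at 2.08-fold, and a median of 0.26 at percentile 99.7, or 0.10 at percentile 91.5 with no filter on dim probes. Nodal and activin targets had a median of 0.21 at percentile 99.1, with Id1 the member past 2-fold of 10, or 0.06 at percentile 86.9 with normexp fitted without the stray signal. Of 23 p53 target genes 3 were higher, Trp53inp1 at 4.32-fold, the pro-apoptotic gene Bbc3 at 2.48-fold and Gadd45a at 2.31-fold, with a median of 0.17 at percentile 99.2, or 0.04 at percentile 87.2 with normexp. Cholesterol biosynthesis genes had a median of 0.35 at percentile 100, with Insig1 2.84-fold higher and the other 24 under 2-fold. With normexp this median was -0.06, still high among random lists at percentile 98.6, and 0.33 at percentile 100 when fitted without the stray signal.

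The remaining lists gave smaller or mixed values on the LIFR knockout array. Primitive streak and mesoderm genes had a median of -0.30 at percentile 1.68 and of -0.24 at percentile 7.34 without the stray signal, outside the central 95% in 4 of 13 alternative settings, with Snai1 4.27-fold higher and Nkx2-5 2.40-fold lower. Among primitive and parietal endoderm genes Plat was 3.08-fold higher, Fst 2.44-fold lower and Thbd at least 2.49-fold lower, with a median of -0.15 at percentile 10.6. Fibroblast and feeder cell genes had a median of -0.05 at percentile 33.6, with Col1a1 3.23-fold higher and Ccl2 lower. Of 30 interferon-stimulated genes Rsad2 was 2.79-fold and Irf1 2.29-fold higher, with a median of 0.04 at percentile 89.6. Of 30 amino acid stress genes Ddit4 was 2.83-fold and Slc7a3 2.12-fold higher, with a median of -0.06 at percentile 6.81, and of 17 genes of the DNA methylation machinery Gadd45b was 2.59-fold higher beside Gadd45a, with a median of 0.02 at percentile 69.3. Wnt targets had a median of -0.07 at percentile 40.9 with Ccn4 2.85-fold higher and Myc lower. Neuroectoderm genes had a median of -0.21 at percentile 17.2.

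Another 7 lists had no member past 2-fold on the LIFR knockout array. Their medians were -0.01 at percentile 79.9 for definitive and visceral endoderm, 0.00 at percentile 58.0 for trophectoderm, 0.00 at percentile 75.7 for germline genes and 0.00 at percentile 79.97 for imprinted genes. Bounds set to 0 can enter these medians, so the values of 0.00 do not show that nothing changed. Glycolysis and hypoxia genes had -0.05 at percentile 9.19, cell cycle genes 0.10 at percentile 96.4 and ribosomal protein genes 0.03 at percentile 34.1. Fewer than 3 of the Y-linked genes and Xist were measured in any comparison, so no median was taken. Requiring both arrays well above background left 253 higher and 177 lower genes. Background correction by normexp gave 3316 and 96, and 110 and 63 when fitted without the stray signal.

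The comparison of the gp130 knockout with wildtype asks the same of the shared receptor subunit. Chemokine and cytokine genes stood among the lowest here too, with Cxcl1 8.30-fold, Csf3 6.18-fold, Cxcl5 5.36-fold and Cxcl3 4.27-fold lower, and Il1a, the gene of interleukin 1 alpha, 3.98-fold lower. Rgs16, a regulator of G protein signalling, was 6.01-fold lower, the zinc exporter gene Slc30a1 5.04-fold lower and Slc16a12, of the monocarboxylate transporter family, 6.30-fold lower, where Slc16a12 had a log2 ratio of 0.08 on the LIFR knockout array. The zinc finger gene Mzf1 was 4.28-fold higher, the carbonic anhydrase gene Car15 3.72-fold, Foxj1 3.64-fold, Bmf 3.56-fold and Cpt1a, whose enzyme brings fatty acids into mitochondria, 3.30-fold higher.

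Of 14917 genes compared, 240 were at least 2-fold higher and 117 at least 2-fold lower on the gp130 knockout array, with 162 and 51 of them resting on a bound. With the wildtype floor of 10.5 only 146 were higher, so this count depends strongly on the floor. Hbp1 was 2.31-fold and Afap1l2 2.28-fold higher. The genes with the highest bounds were Tmc1, Klhl34 and Cfi, at least 10.9-fold, 10.9-fold and 9.88-fold higher, or 7.22-fold, 7.21-fold and 6.53-fold with the floor of 10.5, and Olfr1487, Vmn1r11 and Sertm1, at least 9.19-fold, 4.91-fold and 4.90-fold lower. Of the higher genes, 27 (11.2%) had their spot in a region marked as stray signal, against 1.53% of all genes compared. Without the marked spots, 215 higher and 115 lower genes were counted. Local background on the gp130 knockout array reached only 51, against 25884 on the LIFR knockout array. Whether the marked spots of this comparison hold stray signal was not checked with other probes.

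LIF-STAT3 target genes lay slightly lower on the gp130 knockout array. Of 22 measured members the feedback inhibitor gene Cish was 2.04-fold lower and Pramel7 at least 2.21-fold higher, or 1.46-fold with the floor of 10.5, with Socs3 at a log2 ratio of -0.28 and Cebpb at 0.11, and the median of -0.07 lay at percentile 2.38. Of 12 gp130 family genes Lif was 3.25-fold and Il6 at least 3.70-fold lower, with a median of -0.14 at percentile 3.92. JAK-STAT components had a median of -0.10 at percentile 1.85 with no member past 2-fold, outside the central 95% in 7 of 13 alternative settings. None of the 17 naive or 16 general pluripotency genes passed 2-fold, with medians of -0.01 at percentile 39.2 and -0.00481 at percentile 32.3, where Klf5 had -0.32, Zfp296 -0.59, Cdh1 0.13 and Mybl2 0.000197. These lists were partly above background, as on the other arrays.

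MEK-ERK response genes were again lower on the gp130 knockout array, with a median of -0.41 below all 10000 random lists. Of 22 measured members 4 were lower and none higher, namely Egr1 at 2.75-fold, Dusp5 at 2.43-fold, Fosl1 at 2.26-fold and Egr2 at a bound of 2.64-fold. Cell cycle genes had a median of 0.23 and cholesterol biosynthesis genes of 0.26, both at percentile 100 with no member past 2-fold. Definitive and visceral endoderm genes had a median of 0.44 at percentile 99.9, also with none past 2-fold, among them Gata6 at 0.44 and Apoe at 0.46, and the median fell to 0.12 with no filter and to 0.17 and 0.16 with the 2 normexp settings. Amino acid stress genes had a median of -0.13 at percentile 0.01, with Chac1 2.28-fold lower and Slc7a3 2.41-fold higher of 30. The 5 genes of the 2-cell-like state had -0.24 at percentile 1.27, which turned to 0.10 with normexp, and glycolysis and hypoxia genes -0.02 at percentile 2.45, both with no member past 2-fold. These 2 lists lay outside the central 95% in 8 and 3 of 13 alternative settings.

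BMP targets did not stand apart on the gp130 knockout array, with Id1 2.20-fold lower and a median of -0.06 at percentile 11.2. Nodal and activin targets had -0.06 at percentile 16.7, again with Id1 lower. Of 23 p53 targets Trp53inp1 was 2.07-fold and Gadd45a 2.05-fold higher, with a median of 0.02 at percentile 48.4, and Gadd45a was the member past 2-fold of the DNA methylation machinery, with 0.05 at percentile 62.1. Wnt targets had 0.07 at percentile 69.6, with Ccn4 2.17-fold higher and Axin2 at a bound of 3.33-fold, or 2.20-fold with the floor of 10.5. The Axin2 probe lay in a region marked as stray signal. Primitive and parietal endoderm genes had -0.02 at percentile 19.5, with Fst 3.28-fold and Thbd at least 3.74-fold lower. Fibroblast and feeder cell genes had 0.00150 at percentile 26.6, with Dcn 2.08-fold higher and Ccl2 3.28-fold lower. Trophectoderm genes had 0.12 at percentile 90.1 with Tfap2c at least 2.25-fold lower, and germline genes 0.09 at percentile 71.7 with Fkbp6 at least 2.48-fold higher, or 1.64-fold with the floor of 10.5.

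The other lists had no member past 2-fold on the gp130 knockout array. Their medians were 0.05 at percentile 66.2 for formative and primed epiblast, 0.06 at percentile 73.5 for primitive streak and mesoderm, -0.02 at percentile 42.4 for neuroectoderm and 0.05 at percentile 66.6 for interferon-stimulated genes. Imprinted genes had -0.03 at percentile 28.9 and ribosomal protein genes 0.13 at percentile 96.4. Requiring both arrays well above background left 78 higher and 66 lower genes. With normexp 10 genes were higher and 33 lower, and with normexp fitted without the stray signal 9 and 32.

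**Figure D3:**
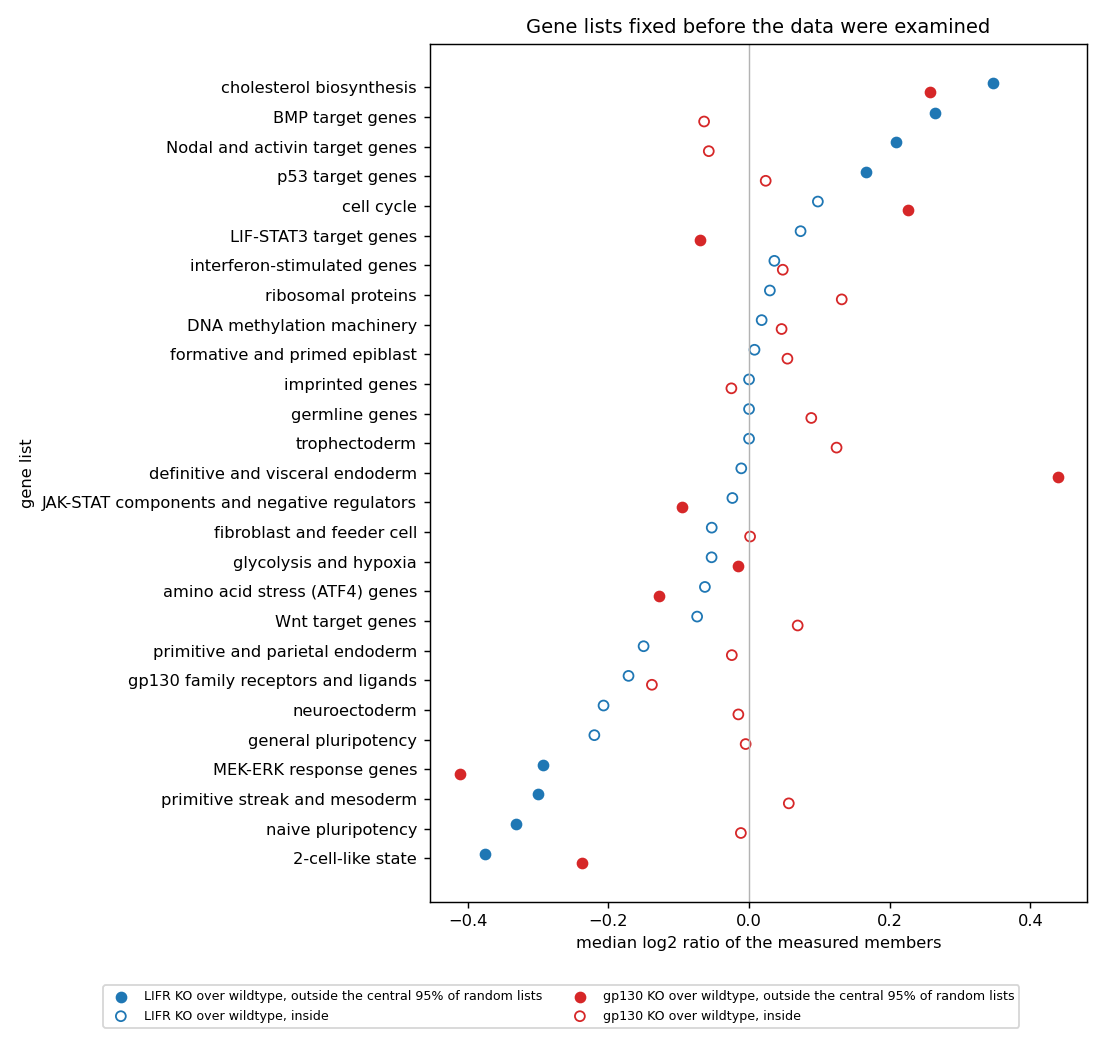
Median log2 ratio of the measured members of each gene list fixed before the data were examined, for the LIFR knockout and the gp130 knockout over wildtype, with filled points outside the central 95% of 10000 random lists. Cholesterol biosynthesis genes lay at 0.35 and 0.26, and MEK-ERK response genes at -0.29 and -0.41.

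Both knockouts were then set beside each other. Cytokine and chemokine genes led the genes lower on both arrays, with Cxcl1, Csf3, Cxcl5, Cxcl3, Ccl2 and Lif the 6 named by rule. Foxj1, Bmf, Frat1, Car15, Cpt1a and Tmprss11f, a gene of a membrane serine protease, led the genes higher on both, with Frat1 10.4-fold and 3.52-fold and Tmprss11f 4.60-fold and 3.14-fold higher on the LIFR and gp130 knockout arrays. In all 58 genes were at least 2-fold higher and 59 at least 2-fold lower than wildtype on both arrays, or 59 and 58 without the stray signal and 45 and 59 with the floor of 10.5. Other probes of Cpt1a gave log2 ratios of 1.06 and 0.83, and of Tmprss11f 1.77 and 0.999.

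Both ratios share the wildtype array, which alone makes them move together. Independent lists would have shared 2.04 higher and 1.91 lower genes. Of 13121 genes measured on all 3 arrays, 38 were higher and 28 lower on both. Unchanged arrays simulated with the scatter seen between the knockout arrays shared a mean of 45.7 and 45.6 and at most 64. That scatter includes the stray signal and may hold real differences between the knockouts, so these simulated counts may be too high. Ratios sharing the LIFR knockout array had a covariance of 0.134, and those sharing the gp130 knockout array 0.0143. The simulation drew the scatter of every array from the same ratios. The counts therefore do not show an overlap below chance. Across genes, which are not independent replicates, the ratios correlated with r = 0.520, against 0.503 in the simulation, with a covariance of 0.0659 against 0.0737. Without the stray signal the shared counts were 39 and 28 against means of 36.5 and 36.2. The correlation was then r = 0.566 against 0.499 in the simulation, and the covariance 0.0672 against 0.0589. With 1 wildtype array the control could not be split, and part of the overlap may come from it.

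**Figure D4:**
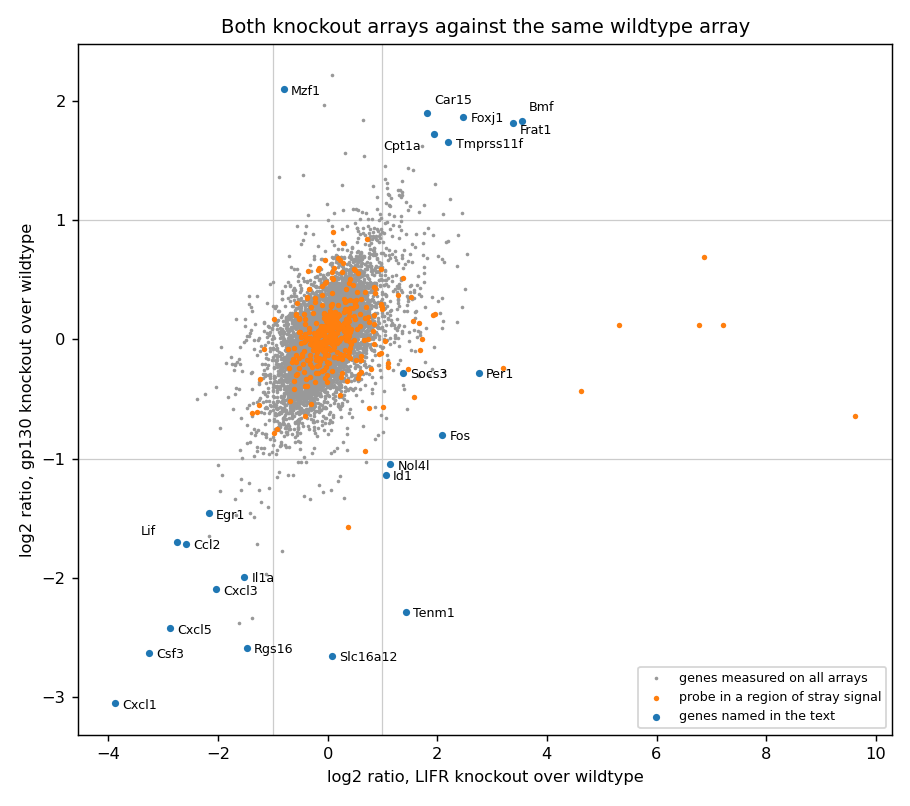
Log2 ratio of each gene for the gp130 knockout over wildtype against that for the LIFR knockout over wildtype, with 1 point per gene measured on all 3 arrays and probes in stray signal in orange. Cxcl1 lies lowest of the labelled genes on both axes, at -3.87 and -3.05, and Bmf lies at 3.55 and 1.83.

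The last comparison asks where the gp130 knockout array differed from the LIFR knockout array. Tenm1, a gene of the teneurin family of cell adhesion proteins, was 13.1-fold lower on the gp130 knockout array, Per1 8.22-fold, Fos 7.44-fold and Slc16a12 6.67-fold lower. Mzf1 was 7.47-fold higher. The other 7 genes that the naming rule gave on the higher side were replication-dependent histone H2A genes. They were H2ac22, H2ac11, H2ac15, H2ac12, H2ac10, H2ac20 and H2ac19, from 3.14-fold for H2ac22 to 2.61-fold for H2ac19. The rule required 2-fold also with normexp fitted with the stray signal, which kept only 16 of the 191 higher genes. Of the 191, 17 were at least 4-fold higher, 13 of them by a bound, so larger ratios than those of the histone genes were passed over. Id1, a target of BMP signalling, and Nol4l were 4.57-fold lower each, and with Tenm1 they were the 3 genes at least 2-fold higher than wildtype on the LIFR knockout array and at least 2-fold lower on the gp130 knockout array.

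Of 14768 genes compared, 191 were at least 2-fold higher and 303 at least 2-fold lower on the gp130 than on the LIFR knockout array, with 67 and 119 of them resting on a bound. Of the 303 lower genes 92 (30.4%) lay in stray signal, among them Npc1l1, Ubxn7, Sord, Sap30bp and Rnft1, and 186 higher and 213 lower genes were counted without it. Then Fsip2l at 5.28-fold and Slc8a1, the gene of a sodium-calcium exchanger, at 4.65-fold stood among the 8 lowest. The histone genes are near-identical copies whose probes may bind each other's transcripts, so that single members are uncertain. Their 11 measured members had a median log2 ratio of -1.61 on the LIFR knockout array and of -0.19 on the gp130 knockout array over wildtype, with the same signs under every scaling tried.

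Some signalling lists differed between the knockout arrays. LIF-STAT3 targets were lower on the gp130 knockout array, with a median of -0.13 at percentile 0.08 and 6 of 22 members lower against 1 higher, among them Socs3 at 3.14-fold lower. BMP targets had -0.22 at percentile 0.03, which turned to 0.10 with no filter on dim probes, with Id1, Id2, Hey1 and Smad7 lower and Id4 higher of 14. Nodal and activin targets had -0.23 at percentile 0.13, or -0.05 at percentile 5.54 with normexp fitted without the stray signal. The p53 targets had -0.15 at percentile 0.11, with 4 of 23 lower, namely Bbc3, Btg2, Trp53inp1 and Cdkn1a. Over 13 alternative settings the p53 median rose to -0.03 and its percentile to 6.3 at most, and it lay outside the central 95% in 12. Primitive streak and mesoderm genes had 0.35 at percentile 99.8, with Snai1 lower and Bmp4 higher. Over 13 alternative settings this median fell to 0 and its percentile to 96.8 at the lowest, and it lay outside the central 95% in 11. Cell cycle genes had 0.11 at percentile 99.6 and ribosomal protein genes 0.11 at percentile 99.1, both with no member past 2-fold, the latter outside the central 95% in 9 of 13 alternative settings. Cholesterol biosynthesis genes had -0.06 at percentile 1.04. With normexp this was 0.22 at percentile 27.2, and -0.07 at percentile 1.43 when fitted without the stray signal.

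The other measured lists lay inside the central 95% of random lists between the knockout arrays. Naive and general pluripotency genes had medians of 0.20 and 0.14 at percentiles 95.3 and 84.9, and MEK-ERK response genes 0.12 at percentile 87.3. Requiring both arrays well above background left 124 higher and 184 lower genes. With normexp the counts were 49 and 3261, and 37 and 74 when fitted without the stray signal.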

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

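Every test in this part was chosen after the stray signal and the opposite ratios had been seen. The highest local background around a spot of the LIFR knockout array, 25884, drew attention because it lies in a column that the main comparisons do not use, though the normexp alternative and the marking of stray signal do, and far above the highest value of 57 on the wildtype array. Tenm1, Id1 and Nol4l drew attention because they were higher than wildtype on the LIFR knockout array and lower on the gp130 knockout array. Their log2 ratios of the gp130 over the LIFR knockout were -3.71, -2.19 and -2.19, and this difference between the knockouts was not tested, since each rests on 1 array per genotype. Tenm1 had signals of 67.6, 205 and 13.6 on the wildtype, LIFR knockout and gp130 knockout arrays. The median spot signals of these arrays were 45.7, 45.9 and 44.1, so only its gp130 knockout value lay under the median.

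The 91 higher genes of the LIFR knockout array that lie in stray signal form the first pattern weighed. Of these, 9 have another measured probe outside the region, and the median log2 ratio of those other probes was -0.01, against 4.63 for the probes of the same 9 genes in the region. The LIFR genotype as the source of these ratios is argued against, since 0 of the 9 genes had other probes at least 2-fold higher, though those of 1 gene, at 0.97, lay just under. Stray light or dirt on the array may thus account for them, as far as 9 genes can speak for 91. For comparison, the 44 higher genes outside the region with another probe had medians of 1.32 and 0.80.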

How the results depend on the processing

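Leaving out stray signal, fitting normexp without it and taking the floor of a bound from single spots were chosen after seeing the data. Counts are given as higher and lower for the LIFR knockout, the gp130 knockout, the gp130 over the LIFR knockout, and both knockouts over wildtype. They stayed within 1.5 times the main counts under median scaling, quantile, cyclic loess, the series matrix, the mean of probes, kept outliers and leaving out stray signal. With normexp they were 3316 and 96, 10 and 33, 49 and 3261, and 6 and 15. Fitted without stray signal, normexp gave 110 and 63, 9 and 32, 37 and 74, and 5 and 19. The count of 3316 thus depended on the stray spots being in the fit, and the offset of 50 shrinks the ratios of dim genes by construction. With both arrays required well above background, which removes bounds by construction, the LIFR higher count was 253, and the others 78 and 66, 124 and 184, and 38 and 28. With no filter they were 649 and 1018, 654 and 594, 969 and 564, and 126 and 271, and the cause was not tested. In the upper 75% of mean signal they were 212 and 141, 36 and 43, 89 and 152, and 21 and 24, with fewer genes compared. With the floor of a bound at the lowest spot in place of the lowest probe, the higher counts were 381, 146 and 45 for the LIFR knockout, the gp130 knockout and both, and the others did not change, since this floor differed on the wildtype array alone. At 4-fold, fewer by construction, they were 103 and 17, 37 and 18, 17 and 66, and 1 and 6, and without stray signal 53 and 18, 34 and 18, and 17 and 28 for the first 3.

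The share of higher genes among calls was 63.9% for the LIFR knockout, 75.9% with cyclic loess and 97.2% with normexp, and turned to 38.9% with no filter. It was 67.2% for the gp130 knockout, 56.1% with the series matrix, 55.5% with the other floor and 52.4% with no filter, and turned to 45.6% in the upper 75% of mean signal, 23.3% with normexp and 22.0% with normexp fitted without stray signal. Between the knockouts it was 38.7%, 1.480% with normexp, and turned to 63.2% with no filter.

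Of the 25 list medians outside the central 95%, all kept their sign under median scaling, cyclic loess, probe means, kept outliers, both other filters, the other floor and without stray signal, and 24 under quantile and the series matrix, 23 with no filter, 19 with normexp and 24 with normexp fitted without stray signal. The naive list on the LIFR knockout array reversed to 0.34 with normexp, at percentile 8.02 of random lists, and 0.0506 with no filter, and lay outside the central 95% in 6 of 13 settings. Other lists that often fell inside were primitive streak and mesoderm on the LIFR knockout array, outside in 4 of 13, glycolysis and hypoxia, JAK-STAT components and the 2-cell-like list on the gp130 knockout array, in 3, 7 and 8, and ribosomal proteins between the knockouts, in 9. The remaining lists of the 25 stayed outside in at least 11 of 13. Cholesterol genes reversed to -0.0560 on the LIFR knockout array and 0.22 between the knockouts with normexp, at percentiles 98.6 and 27.2. Fitted without stray signal, normexp gave -0.211, 0.334 and -0.0671 for these 3, so their reversals depended on the stray spots being in the fit. The 2-cell-like list on the gp130 knockout array reversed to 0.10 with normexp and 0.0939 when fitted without stray signal, and BMP targets between the knockouts to 0.10 with no filter. The cause of the reversals with no filter and of the 2-cell-like list was not tested. With random lists not matched on signal 18 of the 25 stayed outside.

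Of 114 named ratios past 2-fold, 114 stayed so under median scaling, quantile, cyclic loess and kept outliers, 113 with the series matrix and with the other floor, 111 with probe means and 82 with normexp, and 71 of 106 with normexp fitted without stray signal. Clcf1 and Nkx2-5 reversed to 0.29 and 0.39 on the LIFR knockout array with normexp, and did not reverse when it was fitted without stray signal, so this too depended on the stray spots. Without stray signal 99 of 106 stayed, and Rnft1, Ubxn7 and Zbtb46 reversed to -0.00394, -0.00508 and -0.0214 on the LIFR knockout array and Ubxn7 to 0.17 between the knockouts, since another probe then stood for the gene. With normexp fitted without it Ubxn7 reversed to -0.0155 and 0.115 and Zbtb46 to -0.0677, for the same reason.

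Centring on the spike-in probes was not run, because 14.7%, 4.69% and 17.8% of their spots were well above background on the wildtype, LIFR knockout and gp130 knockout arrays. With 1 array per genotype no array was left out. Signal over background limits what can be seen, since 162 of the 240 genes higher on the gp130 knockout array rest on a bound.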

Other observations

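The tests on the loss of the receptors, on array sensitivity, on the scatter of single spots, on the cytokine genes not seen before and on the state of the wildtype culture were chosen after the results were seen. The marker and cytokine lists were also written after the detection values and the shared lower genes had been seen. For the cytokine list the value printed was changed from the percentile to the median after both were known.

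Genes known as targets of the inflammatory regulator NF-kB stood among the genes lower on both knockout arrays. A list of 35 NF-kB and inflammatory cytokine genes on the array was written after those genes had been seen and holds many of them, so that its values as a whole test nothing. Of its genes 16 of 32 measured were at least 2-fold lower and none higher on the LIFR knockout array, and 14 of 33 lower and none higher on the gp130 knockout array. Of the 22 that are not shared lower genes, 3 of 19 and 1 of 20 measured were lower and none higher. Ptgs2, the gene of the prostaglandin enzyme COX-2, had log2 ratios of -1.93 on the LIFR and -1.14 on the gp130 knockout array, the collagenase gene Mmp13 -1.08 and -1.25, and the chemokine gene Ccl7 -2.17 and -1.65. The NF-kB inhibitor genes Nfkbia and Tnfaip3 had -1.29 and -1.42 on the LIFR and -0.90 and -0.86 on the gp130 knockout array. Ccl5 at 0.08 on both and Sod2 at 0.36 and 0.14 did not go with them.

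Probes without a gene name also differed, with 154 higher and 169 lower of 6692 on the LIFR knockout array without the stray signal, and 141 and 63 of 7049 on the gp130 knockout array. Between the knockout arrays 152 were higher and 103 lower of 6758.

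The genes lower than wildtype on both arrays form the second pattern weighed. Lower activity of NF-kB and inflammatory cytokine genes is a candidate explanation, since the list's members outside the shared lower genes had a median of -0.59 on the LIFR and -0.52 on the gp130 knockout array. As some of these had been seen among called or named genes or are in the fixed lists, the 14 measured members that were none of these were taken alone, and had medians of -0.24 at percentile 0.86 and -0.52 below all 10000 random lists. Scatter of single spots is argued against for the 5 shared lower genes read from 10 spots each, Acod1, Ccl2, Csf2, P2ry6 and Ptgs2, since in all 5 every wildtype spot kept lay above every spot kept of both knockout arrays. It stays open for the 54 read from 1 spot. Of these, 20 were measured on all 3 arrays with a wildtype signal of at least 100, where repeated spots, with 7 of 6273 at least 2-fold above the others of their probe, would give 11.3 with an upper limit of 23.3, and the dimmer ones were not tested. Noise of single probes stays open too, because only 3 shared lower genes had another measured probe, with a median of -0.32 on the LIFR knockout array. Of the shared lower genes, 28 were measured on all 3 arrays, beside a simulated mean of 45.6, or 36.2 without the stray signal. These means may be too high, as the ratios between the knockout arrays behind them may hold real differences. Since both ratios use the single wildtype array, the state of that culture cannot be told apart from the genotypes. A lower response through the receptors, as the design names, stays untested for the same reason.

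The pluripotency genes near background on all 3 arrays form the third pattern weighed. Loss of the receptors is argued against as their cause, since only 15 of 27 embryonic stem cell genes were well above background on the wildtype array itself, with 11 on no array. These genes had been seen before, but the naive list fixed beforehand had 17, 16 and 17 of 27 well above background on the wildtype, LIFR knockout and gp130 knockout arrays, about as many with the receptors as without, going by the labels. RNA of epithelial cells in place of embryonic stem cells is a candidate explanation, as 100% of 24 epithelium genes were well above background on the wildtype array, with Krt18 at 39533, Lsr at 15958 and Cldn3 at 12889, against 66.7% of fibroblast, 63.6% of blood, 50% of muscle, 40% of neuron, 22.2% of hepatocyte and 20% of endothelium genes, while stratified epithelium had 87.5%. Against a full replacement stand embryonic stem cell genes detected on the wildtype array, Lin28a at 727, Tdgf1 at 508, Dnmt3b at 319, Sall4 at 312 and Utf1 at 220. Tdgf1 and Sall4 had 3 probes each, of which only 1 each was well above background on any array. Single genes of other lists were as bright on the wildtype array, such as Tnnt2 of muscle at 3714, Kdr of endothelium at 1080 and Snap25 of neurons at 530. Of these lists, 4 of 8 muscle, 6 of 10 endothelium and 4 of 10 neuron genes were detected on no array. The signals of a few embryonic stem cell genes thus do not by themselves show that such cells were present. The replacement remains a hypothesis, because embryonic stem cells are themselves known to express Cdh1, Epcam, Krt8 and Krt18. Also, 5 of the epithelium genes are in the fixed lists, and no sort or gate is named. Low sensitivity stays open, since 55.6% of the embryonic stem cell list was detected against 69.7% of all named genes and the 27 genes had 39 probes, 20 of them well above background on any array.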
